A study of Caenorhabditis elegans with 27 samples.

How the data were processed

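RNA of whole N2 worms was sequenced at days 1, 6, 11, 15 and 17 on OP50 alone and at days 6, 11, 15 and 17 on OP50 with the extract, in 9 groups of 3 libraries. Per the labels, synchronized L4 worms were kept at 20 °C, about 1000 worms went into a sample, and 1 µg of total RNA was made into a library with the MGIEasy kit and sequenced on a DNBSEQ-T7. The deposited table holds raw counts per gene, with no normalization, for 46934 WormBase gene IDs in 27 columns, and every column was matched to a library by diet, day and replicate number. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2 2.0.5, SAMtools 1.7 and featureCounts were used. The parameters of these tools, whether counting was strand-specific, how read pairs were counted, and the genome build and annotation are not given in the sources used here. Of counts between 1 and 20, between 54.5% and 68.9% per library were even, so a count need not stand for 1 fragment.

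Of the gene IDs in the table, 44113 had a symbol in the gene name table and 46924 were found in the WBcel235 annotation, which supplied gene classes and coordinates. No counts stood in entries that name no gene. Library totals ran from 101.61 to 164.34 M counts, with a median of 137.09 M, and rRNA genes held between 0.0755% and 1.27% of them. Replicate libraries were checked for copies of one another, and none were found.

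Differential expression was computed in R 4.3.3 with edgeR 4.0.16, from counts with TMM normalization, a filter on low counts (filterByExpr with the groups, minimum count 10) and a quasi-likelihood fit of 9 group means over the 27 libraries. The filter left 19290 genes, which held at least 99.987% of the counts of each library. The contrasts were BRE against OP50 at each of days 6, 11, 15 and 17, the average of these 4 differences, a joint test of whether they differ between days, the difference at day 17 minus that at day 6, and OP50 at days 6, 11, 15 and 17 against day 1. The last 4 share the day 1 libraries and were not compared with one another. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. With no difference, a share of 0.05 of the genes tested would be expected at an unadjusted p under 0.05. Log2 CPM used a prior count of 2. CPM values are group means with the SD of 3 libraries.

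The 37 gene lists were written from general knowledge of the worm before the counts were seen, and all had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast. Counts adjusted over the list alone use the adjusted p recomputed within the list. For genes that change with age, sets of genes called at 2-fold or more were tested with camera in the BRE contrasts, from OP50 day 17 against day 1, or from day 15 for BRE at day 17.

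Genes were named by a rule written before the counts were seen. Among called genes with a log2 difference of at least 1, a mean of at least 5 CPM in a group and no overlap between the groups, it takes the 8 named genes with the largest rise and the 8 with the largest fall, and 2 of each without such a name. It adds up to 4 members of each called list by adjusted p, and 5 genes for the difference between days. The averaged contrast used it without the overlap condition. Genes outside the rule are described as chosen after their values were seen.

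The fit was tested on simulated data, with counts drawn at the depth and spread of these libraries and 100 genes changed per size. For BRE against OP50 on a single day it called between 34% and 36% of the 2-fold and between 64% and 75% of the 4-fold changes. In the averaged contrast it called 73% and 91%, and in the difference between days 20% and 53%. At day 6, 5 of 105 edgeR calls were false, and 26 of 141 DESeq2 calls. In the averaged contrast 12 of 176 edgeR calls were false. Each gene was drawn independently, with no effect shared within a library or replicate number. These shares need not hold where genes move together. Of 37 unchanged lists camera called 0. Those lists held random genes simulated independently, so this does not show how often camera calls unchanged lists whose members move together. The SE was taken as the absolute log2 difference over the square root of the test's F statistic. The 95% intervals used the normal distribution and are approximate. The median SE of a log2 difference was 0.299 at day 6, 0.298 at day 11, 0.297 at day 15 and 0.148 in the averaged contrast, and the 95% interval lay inside 2-fold for 62.1%, 61.6%, 63.2% and 84.6% of genes (59.9% at day 17).

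Whether libraries of the same number on the same day form pairs was checked from the correlation of their deviations from the group means. At days 6 (0.22, 0.19 and 0.31) and 11 (0.50, 0.41 and 0.22) each of the 3 was over 0.1. The highest other correlation was -0.02 at day 6 and 0.23 at day 11, so pairing is less clear at day 11. A fit with a block within the day stands beside the results of days 6 and 11 where it changed a call. At days 15 (0.04, 0.03 and -0.18) and 17 (0.03, 0.37 and -0.00) they did not all exceed it, nor did those of the OP50 ageing contrasts. There the libraries were taken to share only a number. The check cannot show a difference of replicate 1 that runs through the OP50 days alone. Ribosomal protein medians had one, between 0.3 and 0.76 in the 4 OP50 replicate 1 libraries of days 6 to 17 and between -0.25 and -0.11 in the 8 others. The reported fit does not take it out. The transcript of idpp-1 was highest in replicate 2 in each OP50 and BRE group of days 6 to 17. The averaged contrast takes libraries of different days as independent, so its SE and adjusted p do not allow for series over days.

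Alternatives fixed before the counts were seen were RLE size factors, no filter, DESeq2 1.42.0, only the libraries of a contrast, replicate blocks over all libraries and within the day, a 2-fold threshold, leaving out each library in turn, an estimated correlation, fry and other sets of age-changed genes. Leaving out the libraries rich in sperm transcripts, an estimated correlation for the age-changed sets against day 1 or from later days, and the block within the day for named genes were added after seeing the data. Reads, splicing and the worms' lifespan were not analysed here. No library was left out of the reported contrasts.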

Results

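Whole worms of the Caenorhabditis elegans wild-type strain N2 were sequenced as they aged, on a diet of Escherichia coli OP50 alone or on OP50 with black rice extract (BRE). The 27 libraries fell into 9 groups of 3, which the labels call biological replicates. The OP50 groups, 15 libraries in all, covered days 1, 6, 11, 15 and 17, and the BRE groups, 12 libraries, covered days 6, 11, 15 and 17. Day 1 had no BRE group, so the extract was compared with OP50 alone from day 6 on. The labels name extract concentrations of 0, 0.42, 1.04 and 1.67 mg per mL and do not say which of them the sequenced worms received. The deposited counts summed to between 101.61 and 164.34 M per library, with a median of 137.09 M, and 19290 of the 46934 genes in the table had counts enough to test. Levels are given in CPM, counts scaled to the library's normalized total. Differences are log2 fold changes from edgeR, with a standard error (SE) worked out from the F statistic of the test.

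Age set the libraries apart more than diet did. The first principal component held 51% of the variance and followed the day from day 6 to day 17, and the second, with 13%, set the day 1 libraries apart from the rest. The 6 vitellogenin genes, which encode the yolk proteins made in the intestine, took 10% ± 0.243 (SD, n = 3) of all counts at day 1 and 0.729% ± 0.291 (SD, n = 3) in OP50 worms at day 17. In BRE worms the same share was 3.91% ± 0.85 at day 6, 2.54% ± 0.446 at day 11, 1.87% ± 0.687 at day 15 and 0.959% ± 0.106 at day 17 (SD, n = 3 each). In OP50 worms of those days it was 3.89% ± 0.69, 2.4% ± 0.49, 1.3% ± 0.353 and 0.729% ± 0.291.

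**Figure D1:**
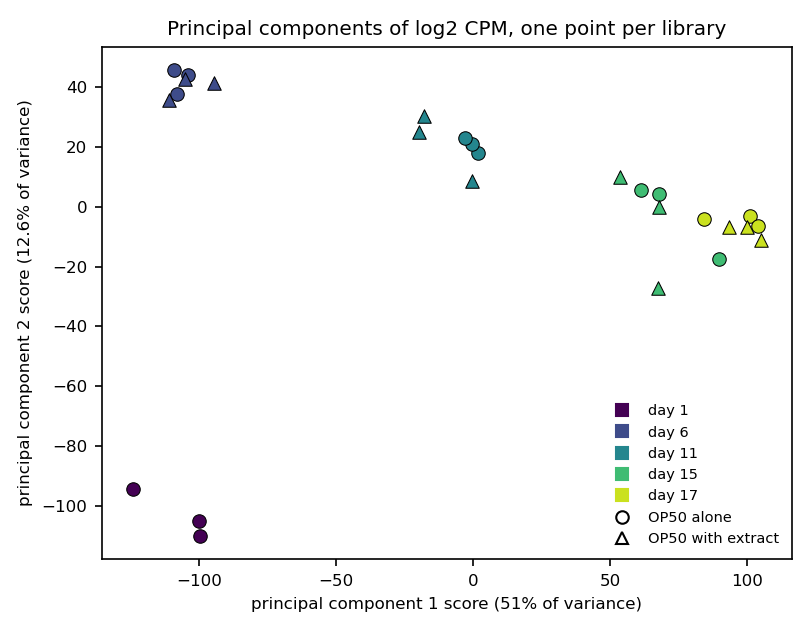
Each point is 1 of the 27 libraries on the first (51% of the variance) and second (13%) principal components of log2 CPM, with colour for the day and symbol for the diet. Libraries of days 6 to 17 spread by day along the first component, and the 3 day 1 libraries stand apart on the second.

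The first comparison asked how gene expression changed with age without the extract, against the only day 1 group. By day 17 the OP50 worms had far less yolk transcript and far more transcript of the lysozyme genes ilys-3 and ilys-2 and of a few genes for antimicrobial peptides. The invertebrate-type lysozyme gene ilys-3 (chromosome IV, 2464456 to 2465443, WBcel235) rose by 10.42 log2 units (SE 0.69, adjusted p = 5.9e-11), from 0.0788 ± 0.0493 to 110 ± 17 CPM (SD, n = 3). The yolk gene vit-1 (chromosome X, 7727889 to 7733168) fell by 8.92 log2 units (SE 0.83, adjusted p = 9.7e-09), from 5663 ± 3061 to 11.7 ± 4.11 CPM. The gene acdh-1 (chromosome I, 6497436 to 6499560), an acyl-CoA dehydrogenase of the pathway that clears propionate, fell by 10.99 log2 units (SE 1.79, adjusted p = 2.4e-05), from 977 ± 99.9 to 0.469 ± 0.305 CPM. In all, 10399 of 19290 genes (53.9%) changed, 5621 upward and 4778 downward, and 6989 of them changed at least 2-fold. Of the other genes with large rises, ilys-2 went from 0.0713 to 91.4 CPM, the cathepsin B-like protease gene cpr-2 from 0.137 to 42.4 CPM, and the caenacin gene cnc-6, an antimicrobial peptide, from 0.133 to 33 CPM. The antimicrobial peptide gene abf-2 went from 0.106 to 18.8 CPM. It overlaps another gene, C50F2.2, and whether counting was strand-specific is not given in the sources used here. C50F2.2 fell with age (-0.58, adjusted p = 0.011), which argues against a fixed share of its reads as the source of the rise. Among the large falls, the collagen gene col-20 went from 430 to 0.0969 CPM and the folate transporter gene folt-2 from 330 to 0.11 CPM.

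Of 37 gene lists, 17 were called at day 17 against day 1, 15 of them lower and 2 higher, and 4 of the calls held with an estimated correlation. These 4 were yolk, the propionate shunt, lipid synthesis and desaturation, and autophagy and lysosome. All 6 yolk genes fell (median -5.87, adjusted p = 1.9e-10, adjusted p = 0.039 with an estimated correlation), vit-2 by 4.26 log2 units from 41903 to 2186 CPM. All 5 genes of the propionate shunt fell (median -2.29, adjusted p = 4.9e-07, and 0.0261 with an estimated correlation), hphd-1 from 392 to 8.1 CPM. In lipid synthesis and desaturation 12 of 16 genes fell and 1 rose (median -0.83, adjusted p = 3.2e-04, and 0.0261 with an estimated correlation), and the desaturase gene fat-7 went from 76.4 to 1.09 CPM. In the autophagy and lysosome list 15 of 29 genes fell and 3 rose (median -0.50, adjusted p = 8.2e-06, and 0.0331 with an estimated correlation). The proton pump subunit gene vha-6 fell from 252 to 19.1 CPM, while the autophagy gene bec-1 rose by 1.24 log2 units (SE 0.12).

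Tissue and immune lists were lower as well at day 17, though their calls were lost with an estimated correlation. Of 14 body wall muscle markers 12 fell (median -2.65, adjusted p = 3.7e-07, adjusted p = 0.274 with an estimated correlation), the myosin light chain gene mlc-2 from 502 to 45.6 CPM. Of 11 intestine markers 8 fell and 1 rose (median -1.44, adjusted p = 5.5e-06, adjusted p = 0.0651 with an estimated correlation), and the protease gene cpr-6 fell by 3.21 log2 units (SE 0.20). Of 10 genes that depend on the p38 kinase PMK-1 in the gut's immune response, 9 fell and none rose (median -5.39, adjusted p = 4.3e-07, adjusted p = 0.0651 with an estimated correlation). Among them C17H12.8 went from 90.7 to 1.72 CPM. Nuclear-encoded oxidative phosphorylation fell in 28 of 42 genes (median -0.54, adjusted p = 1.5e-06, adjusted p = 0.533 with an estimated correlation), gas-1 from 94.5 to 37.3 CPM. Proteasome genes fell in 23 of 33 (median -0.46, adjusted p = 6.2e-05, adjusted p = 0.551 with an estimated correlation). Oocyte and eggshell genes fell in 16 of 22 and rose in 2 (median -0.62, adjusted p = 3.1e-04, adjusted p = 0.551 with an estimated correlation). UDP-glucuronosyltransferases, which conjugate foreign compounds, fell in 33 of 67 and rose in 15 (median -0.71, adjusted p = 0.00856, adjusted p = 0.551 with an estimated correlation).

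Cuticle collagens went both ways, with 43 of 159 lower and 28 higher (median -0.18, mean -1.06, adjusted p = 0.0127, adjusted p = 0.765 with an estimated correlation), and col-8 went from 853 to 3.13 CPM. Their median was -0.0292 without OP50 day 1 replicate 3, -0.0366 without replicate 2 and -0.303 without replicate 1. Fatty acid oxidation and lipolysis fell in 11 of 25 genes and rose in 2 (median -0.44, adjusted p = 0.00305, adjusted p = 0.0874 with an estimated correlation), with a median of -0.124 without OP50 day 17 replicate 1. Genes of the mitochondrial genome were called lower (median -0.75, adjusted p = 0.0426, adjusted p = 0.551 with an estimated correlation). That call was lost without OP50 day 1 replicate 3 (adjusted p = 0.0776) or OP50 day 17 replicate 2 (0.083), and the median was -1.13 without OP50 day 17 replicate 3. C-type lectins were called lower, with 62 genes lower and 49 higher of 176 and a median of -0.06 but a mean of 0.05 (adjusted p = 0.0476, adjusted p = 0.551 with an estimated correlation). The lectin call was lost without OP50 day 17 replicate 2 (0.0711) or 3 (0.081), and their median turned positive without any 1 of the 6 libraries, up to 0.371 without OP50 day 1 replicate 3.

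Histones and insulin-like peptides were the 2 lists called higher. Of 60 histone genes 37 rose and 1 fell (median 1.32, adjusted p = 3.9e-05, adjusted p = 0.533 with an estimated correlation), his-60 from 9.61 to 45.6 CPM. Of 37 insulin-like peptide genes 19 rose and 1 fell (median 1.37, adjusted p = 4.6e-04, adjusted p = 0.24 with an estimated correlation), ins-22 from 0.701 to 13.3 CPM. Lysozymes as a list were not called, with 6 of 15 genes higher and 7 lower (adjusted p = 0.357). By class of gene, 173 of 359 tested ncRNA genes rose and 20 fell, and 49 of 112 lincRNA genes rose and 9 fell.

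The count of changed genes in OP50 worms was 6358 at day 6, with 2694 higher and 3664 lower, 6901 at day 11, with 3705 higher and 3196 lower, and 9103 at day 15, with 5032 higher and 4071 lower. At day 6 muscle, pharynx and neuron markers were low and DAF-16 class I and antimicrobial peptide genes were high, with 7 lists called higher and 13 lower, none of them with an estimated correlation. Of 14 muscle markers 13 fell (median -2.28, adjusted p = 3.0e-10, adjusted p = 0.226 with an estimated correlation), and of 16 neuron markers 13 fell (median -1.29, adjusted p = 2.4e-04, adjusted p = 0.282 with an estimated correlation). Of 14 DAF-16 class I genes, which are raised when insulin signalling is low, 8 rose and 2 fell (median 1.11, adjusted p = 9.5e-05, adjusted p = 0.146 with an estimated correlation). The metallothionein gene mtl-1 rose from 2.24 to 93.1 CPM and the lysozyme gene lys-7 from 35.3 to 707 CPM. Of 49 antimicrobial peptide genes 17 rose and 8 fell (median 0.60, adjusted p = 4.4e-04, adjusted p = 0.48 with an estimated correlation). The PMK-1 list was higher at day 6 (4 genes higher, 1 lower, median 0.78, adjusted p = 0.0292, adjusted p = 0.561 with an estimated correlation), a call lost without OP50 day 1 replicate 1 (0.0532) or 3 (0.102). It was lower at day 11 (7 lower, 1 higher, median -2.46, adjusted p = 0.00532, adjusted p = 0.411 with an estimated correlation) and at day 15 (9 lower, 1 higher, median -5.49, adjusted p = 3.3e-08, adjusted p = 0.0503 with an estimated correlation). Pharynx and neuron markers were called lower at days 6 and 11 and not at days 15 and 17. At day 11, 3 lists were called higher and 14 lower, and at day 15, 2 higher and 16 lower. On each of these days 2 calls held with an estimated correlation, those of the propionate shunt (adjusted p = 0.0204 at day 11 and 0.029 at day 15) and of autophagy and lysosome (0.0204 and 0.0362), whose median at day 11 was -0.30, and -0.459 without OP50 day 1 replicate 3.

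The central question of the series was what the extract changed in worms of the same age. At day 6 the clearest difference was in nlp-26, a neuropeptide-like protein gene, whose transcript stood at 13 ± 1.9 CPM with BRE and 2.65 ± 0.393 CPM on OP50 alone (SD, n = 3 each). This was a rise of 2.27 log2 units (SE 0.33, adjusted p = 0.00531). The gene srlf-12 rose by 2.70 log2 units (SE 0.39, adjusted p = 0.00531), from 0.104 ± 0.0464 to 0.677 ± 0.206 CPM. W03G1.5 rose by 2.40 log2 units (SE 0.39, adjusted p = 0.0171), from 0.778 ± 0.128 to 4.12 ± 2.89 CPM. These 3 were all the genes called over all genes tested, each higher in 3 of 3 BRE libraries than in any OP50 library of the day. In all 463 genes had an unadjusted p under 0.05, fewer than the share of 0.05 expected with no difference. DESeq2 called 13 genes. srlf-12 and W03G1.5 lay outside the fixed rule for named genes at this day and were chosen after their values were seen. Without OP50 day 6 replicate 1 no gene was called by edgeR (adjusted p = 0.0754 for nlp-26 and srlf-12, 0.115 for W03G1.5), and without OP50 day 6 replicate 3 none was either (0.131, 0.131 and 0.394). The W03G1.5 call was also lost without OP50 day 6 replicate 2 (0.167) or BRE day 6 replicate 2 (0.177), and without the 4 libraries rich in sperm transcripts, an alternative chosen after seeing the data. With only the libraries of the 2 groups in the fit 0 genes were called. With libraries of the same number paired within the day, 5 genes were called, idpp-1 and cut-5 being the added ones.

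Glutathione S-transferases, ribosomal proteins, cuticle collagens and zygotic embryo genes were called lower with BRE at day 6 and major sperm proteins higher, 5 of 37 lists in all. None of the 5 held with an estimated correlation (adjusted p = 0.947 for each with an estimated correlation), and no member passed the edgeR test over all genes or adjusted over the list alone. DESeq2 called 4 members over all genes, col-156 and the sperm protein genes msp-142, msp-53 and msp-36. Glutathione S-transferases, enzymes of detoxification, had a median of -0.31 with 9 of 47 genes positive (adjusted p = 1.0e-04), and gstk-1 stood at 20.2 ± 1.34 CPM with BRE and 26.1 ± 3.16 without. Cytosolic ribosomal proteins had a median of -0.16 with 1 of 81 genes positive (adjusted p = 1.8e-04). Without OP50 day 6 replicate 1 their median was 0.0544 (adjusted p = 0.113), without BRE day 6 replicate 3 -0.107 (0.197) and without OP50 day 6 replicate 3 -0.286. Collagens had a median of -0.23 (adjusted p = 0.0171), 0.0494 without OP50 day 6 replicate 1 (0.968) and -0.175 without BRE day 6 replicate 3 (0.715). Without OP50 day 6 replicate 3 or BRE day 6 replicate 1 the collagen median was -0.378 or -0.405. Zygotic embryo genes had a median of -0.39 with 3 of 12 positive (adjusted p = 0.00668), -0.302 without BRE day 6 replicate 2 (0.0865) and -0.184 without OP50 day 6 replicate 1. Major sperm protein transcripts were close to absent, with msp-142 at 0.0641 ± 0.111 CPM with BRE and 0 CPM in the OP50 group. That call (adjusted p = 8.3e-05) was lost without BRE day 6 replicate 3 (0.954). Paired by number, heat shock and chaperone genes were also called lower (median -0.226, adjusted p = 0.00352, against 0.457 unpaired), as were antimicrobial peptides (median -0.142, adjusted p = 0.00469, against 0.138 unpaired).

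At day 11 nlp-26 and srlf-12 were again higher with the extract. nlp-26 rose by 2.69 log2 units (SE 0.34, adjusted p = 9.3e-04), with 8.71 ± 1.3 CPM in BRE worms and 1.35 ± 0.303 CPM on OP50 alone (SD, n = 3 each). srlf-12, chosen after its values were seen, rose by 2.60 log2 units (SE 0.37, adjusted p = 0.00437), with 1.15 ± 0.455 against 0.188 ± 0.0284 CPM. Both were higher in 3 of 3 BRE libraries than in any OP50 library of the day. These 2 were all the genes called; 494 had an unadjusted p under 0.05, and DESeq2 called 7. The srlf-12 call was lost without OP50 day 11 replicate 1 (log2 difference 2.44, adjusted p = 0.0734). With libraries of the same number paired within the day, 3 genes were called, idpp-1 being the added one.

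Immune and detoxification lists leaned upward at day 11, where 7 of 37 lists were called, all higher and none with an estimated correlation. PMK-1 dependent immune genes had a median of 0.86 with 9 of 10 genes positive (adjusted p = 6.1e-06, adjusted p = 0.303 with an estimated correlation). By edgeR no member passed over all genes and 3 rose when adjusted over the list alone. Among its members, clec-85, a C-type lectin gene, stood at 13.3 ± 3.48 with BRE against 7.93 ± 1.84 CPM, and C17H12.8 at 33.2 ± 24.6 against 13.6 ± 3.2 CPM. Without BRE day 11 replicate 3 the PMK-1 median was 0.499 (adjusted p = 0.0115). Antimicrobial peptides had a median of 0.25 with 38 of 49 positive (adjusted p = 3.1e-04, adjusted p = 0.703 with an estimated correlation), lost without OP50 day 11 replicate 2 (0.109) or BRE day 11 replicate 3 (median -0.0463, 0.93). Glutathione S-transferases had a median of 0.26 with 37 of 47 positive (adjusted p = 0.00152, adjusted p = 0.703 with an estimated correlation). That call was lost without OP50 day 11 replicate 2 (median 0.147, 0.115) or BRE day 11 replicate 3 (median -0.0615, 0.93), and the median was 0.152 without OP50 day 11 replicate 3. Lysozymes had a median of 0.28 (adjusted p = 0.00748, adjusted p = 0.562 with an estimated correlation), lost without OP50 day 11 replicate 2 (0.0929) or BRE day 11 replicate 3 (median 0.124, 0.268). The SKN-1 phase II list, the targets of a regulator of detoxification, had a median of 0.26 (adjusted p = 0.0307, adjusted p = 0.703 with an estimated correlation). It was lost without OP50 day 11 replicate 2 (median 0.151, 0.224) or BRE day 11 replicate 3 (median 0.00996, 0.768).

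Lipid synthesis and body wall muscle completed the day 11 calls. Lipid synthesis and desaturation had a median of 0.21 with 12 of 16 genes positive (adjusted p = 0.0474, adjusted p = 0.303 with an estimated correlation). This call was lost without OP50 day 11 replicate 1 (0.172) or 2 (0.199) and without BRE day 11 replicate 1 (median 0.0461, 0.269) or 3 (median 0.136, 0.0545). Muscle markers had a median of 0.37 with 11 of 14 positive (adjusted p = 0.0474, adjusted p = 0.942 with an estimated correlation). Their call was lost without OP50 day 11 replicate 1 (0.169) or 3 (0.235) or BRE day 11 replicate 2 (median -0.211, 0.283), and the median was 0.558 without OP50 day 11 replicate 2 and 0.584 without BRE day 11 replicate 1. Paired by number, DAF-16 class II genes were also called higher (median 0.198, adjusted p = 0.0487, against 0.08 unpaired).

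At day 15 the immune genes that fall with age stood higher in BRE worms. PMK-1 dependent immune genes had a median difference of 2.60 log2 units with 9 of 10 genes positive (adjusted p = 1.6e-34). This call held with an estimated correlation (adjusted p = 2.3e-04). By edgeR no member passed over all genes, and 9 rose and 1 fell when adjusted over the list alone; DESeq2 called 7 over all genes (K08D8.5, C17H12.8, sysm-1, irg-4, dod-22, dod-24 and clec-67). Among the members, sysm-1 stood at 3.7 ± 1.27 CPM with BRE and 0.274 ± 0.202 CPM on OP50 alone (SD, n = 3 each), a difference of 3.70 log2 units (SE 0.73, adjusted p = 0.15). C17H12.8 stood at 11.7 ± 6.84 against 1.91 ± 0.734 CPM, and K08D8.5 at 0.88 against 0.152 CPM. The list was called without each of the 6 libraries in turn, and it was also called as a set by fry (adjusted p = 0.00911).

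Yolk protein genes were higher with BRE at day 15 as well, with a median of 1.23 and 6 of 6 genes positive (adjusted p = 7.0e-15, and 0.0266 with an estimated correlation). vit-3 stood at 214 ± 199 CPM with BRE and 31.5 ± 23.1 CPM without (log2 difference 2.77, SE 0.56, adjusted p = 0.15), and vit-4 at 187 ± 145 against 41.2 ± 28.2 CPM. By edgeR no yolk gene passed over all genes and 3 rose when adjusted over the list alone, while DESeq2 called vit-3 and vit-4 over all genes. With no filter on low counts edgeR called 14 genes, among them vit-3 and the PMK-1 members sysm-1, C17H12.8 and dod-22. Without BRE day 15 replicate 1 the yolk median was 0.381 (adjusted p = 1.1e-05, adjusted p = 0.558 with an estimated correlation). The call with an estimated correlation was also lost without OP50 day 15 replicate 1 (0.133) or 2 (0.3). edgeR called no single gene at day 15, and 546 genes had an unadjusted p under 0.05, fewer than the share of 0.05 expected with no difference. DESeq2 called 59, all higher with BRE, among them collagen genes such as col-166 and col-101. DESeq2 was not run without BRE day 15 replicate 1. edgeR called 3 genes without BRE day 15 replicate 2 (nas-38, C42D4.3 and C17H12.8). Without BRE day 15 replicate 3 it called 5 (col-101, grd-5, F56D6.9, ctsa-1.2 and lgc-21). Genes in these counts were named after their values were seen.

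In all 9 of 37 lists were called at day 15, 7 higher and 2 lower, and the 7 others did not hold with an estimated correlation. Cuticle collagens had a median of 1.13 and a mean of 1.99 with 133 of 159 positive (adjusted p = 5.1e-23, adjusted p = 0.219 with an estimated correlation), and 53 rose when adjusted over the list alone. col-101 stood at 18.7 ± 12.7 CPM with BRE against 5.43 ± 1.05 CPM. Without BRE day 15 replicate 1 the collagen median was 0.0514 (adjusted p = 0.0611). That library, on which the yolk median also leaned, had the highest median of 10 larval moulting genes of all libraries. It was 5.08 log2 CPM, against 4.04 and 3.76 in BRE day 15 replicates 2 and 3. Muscle markers had a median of 0.47 with 14 of 14 positive (adjusted p = 5.2e-06, adjusted p = 0.593 with an estimated correlation), 0.278 without BRE day 15 replicate 1 (0.138) and 0.731 without BRE day 15 replicate 3. Lysozymes had a median of 0.29 (adjusted p = 6.6e-04, adjusted p = 0.219 with an estimated correlation) and 3 rose when adjusted over the list alone, ilys-5 standing at 25.7 against 9.5 CPM. The lysozyme call was lost without BRE day 15 replicate 1 (0.0526), and the median was 0.144 or 0.19 without OP50 day 15 replicate 1 or 3. DAF-16 class II genes had a median of 0.20 and a mean of 1.16 with 4 of 7 positive (adjusted p = 0.00133, adjusted p = 0.219 with an estimated correlation). The 2 that rose when adjusted over the list alone, dod-22 and dod-24, are also members of the PMK-1 list. That call was lost without OP50 day 15 replicate 2 (median 0.0705, 0.135) or BRE day 15 replicate 1 (median 0.0862, 0.0526), and its median was 0.37 without OP50 day 15 replicate 1 and 0.317 without BRE day 15 replicate 2.

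The remaining day 15 lists differed by less. Glutathione S-transferases had a median of 0.15 (adjusted p = 0.0321, adjusted p = 0.786 with an estimated correlation), lost without OP50 day 15 replicate 2 (0.117) or 3 (median 0.0728, 0.235) or BRE day 15 replicate 2 (median 0.0431, 0.0536) or 3 (0.123). Ribosomal proteins had a median of -0.14 with 2 of 81 positive (adjusted p = 3.4e-07, adjusted p = 0.831 with an estimated correlation), 0.00419 without OP50 day 15 replicate 1 (0.807) and -0.26 without OP50 day 15 replicate 3. Major sperm proteins were called lower with BRE (adjusted p = 3.0e-06, adjusted p = 0.786 with an estimated correlation), msp-142 standing at 0.224 ± 0.198 against 1.45 ± 2.18 CPM. That call was lost without OP50 day 15 replicate 3 (0.704), whose sperm protein median was the highest of the 27 libraries, or BRE day 15 replicate 3 (0.0567).

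At day 17 no single gene passed by edgeR, while 1569 genes had an unadjusted p under 0.05 and DESeq2 called 3. Only this BRE contrast had more such genes than the share of 0.05 expected with no difference. Genes are not independent, so the excess is not itself a test. Genes of the longevity and nutrient-sensing list, which holds the insulin and TOR pathways, stood higher with BRE, and histones, antimicrobial peptides and ribosomal proteins stood lower. Of 37 lists 12 were called, 2 higher and 10 lower, and none held with an estimated correlation (adjusted p = 0.688 for FMRFamide-like neuropeptides and 0.68 for each of the 11 others with an estimated correlation). No member of any called list passed by either tool over all genes, or by edgeR adjusted over the list alone. The longevity list had a median of 0.21 with 23 of 26 genes positive (adjusted p = 2.7e-06), 0.11 without OP50 day 17 replicate 1 and 0.395 without OP50 day 17 replicate 2. The insulin receptor gene daf-2 stood at 166 ± 31.9 CPM with BRE against 98.3 ± 36.5 CPM, the TOR kinase gene let-363 at 176 ± 38.9 against 103 ± 35.7 CPM, and the FOXO factor gene daf-16 at 219 ± 30 against 156 ± 42.9 CPM (SD, n = 3 each). Histones had a median of -0.48 with 3 of 60 positive (adjusted p = 4.7e-13), -0.273 without OP50 day 17 replicate 1. Antimicrobial peptides had a median of -0.43 with 6 of 49 positive (adjusted p = 3.9e-06), -0.218 without OP50 day 17 replicate 2 (0.0282), and the saposin-like gene spp-5 stood at 32.9 ± 2.38 against 52.5 ± 6.96 CPM.

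Ribosomal, respiratory and proteasome lists were lower at day 17, and each of these calls ended without the same control library. Ribosomal proteins had a median of -0.40 with 0 of 81 genes positive (adjusted p = 8.5e-20), -0.0439 without OP50 day 17 replicate 1 (0.161). Oxidative phosphorylation had a median of -0.23 (adjusted p = 8.1e-05), 0.0169 without OP50 day 17 replicate 1 (0.961) and -0.371 without OP50 day 17 replicate 3. Proteasome genes had a median of -0.15 (adjusted p = 0.00106), -0.0253 without OP50 day 17 replicate 1 (0.726) and -0.248 without OP50 day 17 replicate 3. That same control library had the highest sperm protein median of its day, 4.45 log2 units above the mean of all libraries. Major sperm proteins were called lower with BRE (adjusted p = 3.9e-06), lost without OP50 day 17 replicate 1 (0.52), with msp-142 at 0.129 ± 0.213 against 1.2 ± 1.86 CPM. Lysozymes (median -0.41, adjusted p = 0.0112) lost the call without OP50 day 17 replicate 2 (0.17) or BRE day 17 replicate 1 (median -0.261, 0.0653). Glutathione S-transferases (median -0.25, adjusted p = 0.00247) lost it without OP50 day 17 replicate 3 (0.104).

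Germline genes (median 0.16, adjusted p = 0.0112) were called higher at day 17, lost without OP50 day 17 replicate 3 (median -0.000971, 0.732) or BRE day 17 replicate 1 (0.0702) or 2 (0.0588), with medians of 0.29 without OP50 day 17 replicate 2 and 0.255 without BRE day 17 replicate 3. Insulin-like peptides (median -0.20, adjusted p = 0.0342) lost the call without OP50 day 17 replicate 2 (0.0752) or 3 (0.152) or BRE day 17 replicate 2 (0.05) or 3 (0.0738). FMRFamide-like neuropeptides (median -0.19, adjusted p = 0.00886) lost it without OP50 day 17 replicate 3 (0.123) or BRE day 17 replicate 1 (median -0.104, 0.0705), and their median was -0.324 without BRE day 17 replicate 2.

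Averaged over days 6 to 17, a small set of genes was higher with the extract. nlp-26 (WBGene00003764, chromosome V, 19613461 to 19614534) rose by 1.85 log2 units (SE 0.16, adjusted p = 1.6e-06) and was above every OP50 library of its day in 11 of 12 BRE libraries. In the remaining one, BRE day 17 replicate 1, it lay below every OP50 library of the day, at 1.34 CPM against 1.4 to 1.92 CPM. srlf-12 (WBGene00045207, chromosome IV, 10891333 to 10892093) rose by 1.93 (SE 0.18, adjusted p = 2.8e-06) and was above in 12 of 12. W03G1.5 (WBGene00021011, chromosome IV, 505069 to 506484) rose by 1.63 (SE 0.19, adjusted p = 5.0e-05) and was above in 12 of 12. The largest averaged rise was in idpp-1 (WBGene00020550, chromosome III, 740682 to 742941), by 4.13 (SE 0.42, adjusted p = 6.4e-06) and above in 12 of 12 libraries, with 4.37 ± 3.94 CPM at day 6 and 2.91 ± 2.97 CPM at day 17 in BRE worms against 0.238 ± 0.141 and 0.138 ± 0.104 CPM. srlf-14 (WBGene00008757, chromosome IV, 10893580 to 10894355) rose by 3.58 (SE 0.42, adjusted p = 6.3e-05, above in 12 of 12) and srlf-3 (WBGene00016180, chromosome IV, 8487483 to 8488490) by 1.00 (SE 0.16, adjusted p = 0.0116, above in 11 of 12). Levels of srlf-14 were low, at 0.219 ± 0.143 CPM with BRE against 0.0252 ± 0.0191 CPM at day 6, and 1.01 ± 0.619 against 0.0996 ± 0.0525 CPM at day 17. These 6 genes were called without each of the 24 libraries in turn. Libraries of the same replicate number were not left out together, and the 12 BRE libraries were counted as if independent.

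Another 3 genes passed the averaged test with less margin. ora-1 (WBGene00003879, chromosome IV, 7977890 to 7979020), named for an Onchocerca antigen, rose by 1.56 (SE 0.28, adjusted p = 0.0348) and was above in 11 of 12 BRE libraries, with 89.8 ± 17 against 26.7 ± 8.5 CPM at day 11 (SD, n = 3 each). scl-25 (WBGene00011841, chromosome V, 17225689 to 17227998), which encodes an SCP-like extracellular protein, fell by 1.99 (SE 0.37, adjusted p = 0.0427) and was below in 11 of 12. Its levels were low, at 0.0534 ± 0.0259 CPM with BRE against 0.608 ± 0.324 CPM at day 6, and 0.124 ± 0.0576 against 0.301 ± 0.1 CPM at day 17. Y38H6A.1 (WBGene00012612, chromosome V, 20325717 to 20328083) was higher (adjusted p = 0.0452) and above in 10 of 12, at 0.141 ± 0.102 against 0.0135 ± 0.0141 CPM at day 17. ora-1 kept its call without 5 of the 24 libraries in turn (OP50 day 15 replicate 2, OP50 day 17 replicate 2, BRE day 6 replicate 1, BRE day 15 replicate 3 and BRE day 17 replicate 1), with adjusted p up to 0.129 without the other 19. scl-25 kept it without 5 (OP50 days 6, 11 and 15 replicate 3, BRE day 15 replicate 2 and BRE day 17 replicate 1; up to 0.122 otherwise), and Y38H6A.1 without 2 (BRE day 6 replicate 3 and BRE day 17 replicate 1; up to 0.15 otherwise). All 3 calls ended without the 4 libraries rich in sperm transcripts, an alternative chosen after seeing the data, and that of Y38H6A.1 also with a replicate block, within the day or over all libraries. In all 9 genes were called, 8 higher and 1 lower, with 705 genes at an unadjusted p under 0.05 and 30 called by DESeq2. The fixed rule named nlp-26, W03G1.5 and ora-1; the 6 others were chosen after their values were seen. nlp-26 overlaps Y43F8C.3, idpp-1 overlaps pat-12 and scl-25 overlaps srh-112 on the opposite strand, so reads of each pair may be shared. With BRE, Y43F8C.3 differed by 0.11 log2 units (SE 0.1, adjusted p = 0.967) and pat-12 by 0.11 (SE 0.11, adjusted p = 0.967). Over all libraries srh-112 held 58 counts, against 998 for scl-25.

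**Figure D2:**
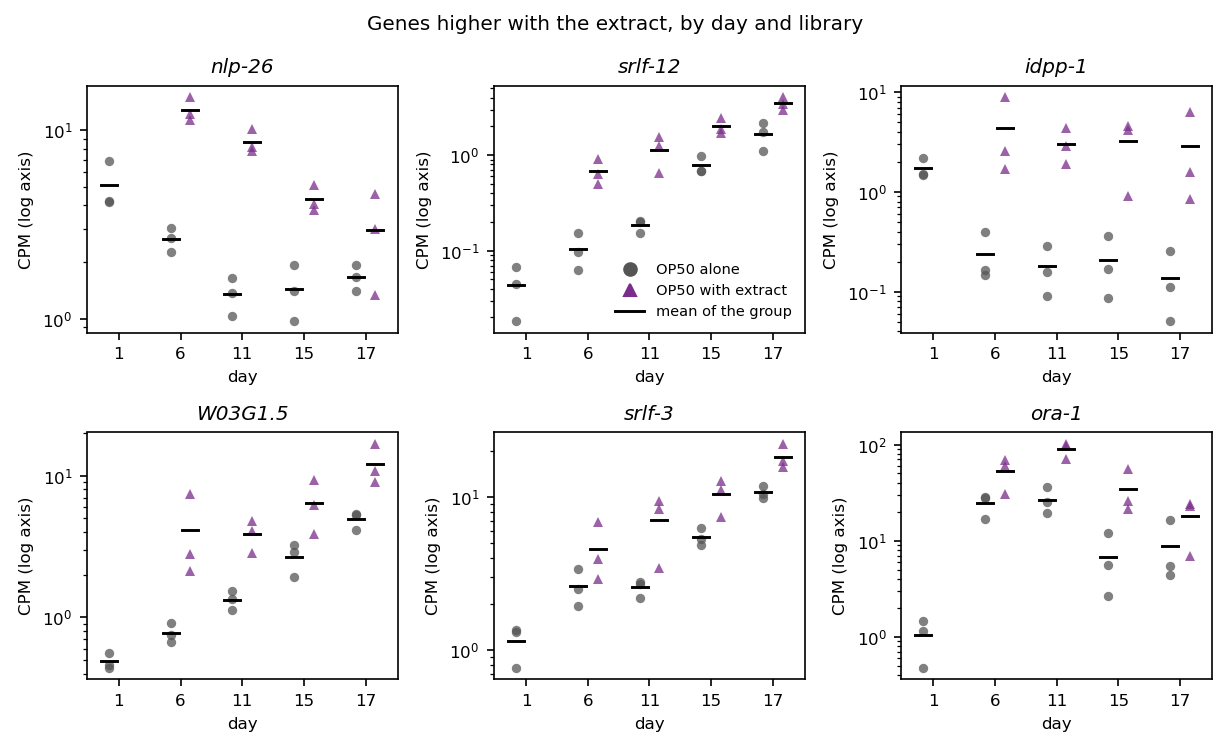
CPM on a log axis of genes called over days 6 to 17, by day, with 1 point per library, bars for the means of 3 libraries, and colours for OP50 and BRE. For nlp-26 the means at day 11 are 8.71 CPM with BRE and 1.35 CPM on OP50 alone, and srlf-12, idpp-1 and W03G1.5 are above every OP50 library of their day in 12 of 12 BRE libraries.

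Among gene lists the averaged contrast had 12 calls, 7 higher and 5 lower with BRE, and none held with an estimated correlation. PMK-1 dependent immune genes had a median of 0.73 with 9 of 10 positive (adjusted p = 5.5e-08, adjusted p = 0.203 with an estimated correlation), and 8 rose and 1, irg-5, fell when adjusted over the list alone. With a block within the day, the medians of this list at days 6, 11, 15 and 17 were -0.253, 0.822, 2.45 and -0.466. In the reported fit the list was not called at day 6 (adjusted p = 0.374) or day 17 (0.105). Yolk genes had a median of 0.44 with 6 of 6 positive (adjusted p = 1.9e-06, adjusted p = 0.301 with an estimated correlation), 2 of them higher when adjusted over the list alone, and a median of 0.224 without BRE day 15 replicate 1. Ribosomal proteins had a median of -0.18 with 0 of 81 positive (adjusted p = 3.8e-19, adjusted p = 0.816 with an estimated correlation), -0.0895 without OP50 day 17 replicate 1. Relative to the mean of all libraries, their median was between 0.3 and 0.76 in the 4 OP50 replicate 1 libraries of these days and between -0.25 and -0.11 in the 8 other OP50 libraries. In BRE libraries it was between -0.19 and 0.16 in the 4 of replicate 1 and between -0.28 and 0 in the 8 others, so the 8 other OP50 libraries lay within the range of the BRE libraries. Histones had a median of -0.13 with 12 of 60 positive (adjusted p = 5.1e-05, adjusted p = 0.816 with an estimated correlation), -0.084 without OP50 day 6 replicate 1. The other 8 calls each ended without at least 1 of the 24 libraries. Antioxidant enzymes, DAF-16 class I genes and cytochrome P450 genes were not called in the averaged contrast, and mtl-1 differed by -0.52 (SE 0.18, adjusted p = 0.967).

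Whether the effect of the extract changed with age was tested directly. No gene passed the edgeR test of a difference between the 4 days; 579 had an unadjusted p under 0.05 and DESeq2 called 8. For nlp-26 the log2 difference was 2.27 (SE 0.33) at day 6, 2.69 (SE 0.34) at day 11, 1.59 (SE 0.32) at day 15 and 0.84 (SE 0.32) at day 17, and the test of their difference gave an unadjusted p of 0.00259 and an adjusted p of 1. The smallest adjusted p was 0.313, for idpp-12, fbxa-154 and F56D6.9. For day 17 against day 6 alone no gene passed by edgeR, with 353 at an unadjusted p under 0.05 and 6 called by DESeq2. At that depth and number of libraries the median SE of this difference was 0.422, and 46.3% of genes had a 95% interval within 2-fold, against 84.6% in the averaged contrast and 62.1% at day 6 alone.

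The last comparison asked whether the extract moved genes along or against their change with age. The sets held 4520 genes raised and 2469 lowered at least 2-fold in OP50 worms at day 17 against day 1, and for BRE at day 17 they came from day 15, with 4026 and 2098 genes, so that no library stood in both comparisons. Age-lowered genes were higher with BRE at day 11 (median 0.12, 67.3% positive, adjusted p = 7.3e-05, adjusted p = 0.242 with an estimated correlation) and at day 15 (median 0.16, 75.3% positive, adjusted p = 1.5e-12, adjusted p = 0.0555 with an estimated correlation). Age-raised genes were lower at day 11 (median -0.06, adjusted p = 1.1e-04, adjusted p = 0.136 with an estimated correlation) and at day 15 (median -0.04, adjusted p = 0.00744, adjusted p = 0.242 with an estimated correlation). With sets taken at adjusted p alone these calls stayed. The medians were then 0.0481 and 0.0719 for age-lowered genes at days 11 and 15, and -0.0195 and -0.0433 for age-raised genes. At day 6 the medians were -0.04 for age-raised genes (adjusted p = 0.712) and -0.08 for age-lowered genes (0.156). At day 17 they were 0.01 (0.817) and -0.06 (0.0812), and none of these 4 was called. With the sets taken from OP50 day 15 against day 11 instead, age-lowered genes were called lower with BRE at days 6 (median -0.176, adjusted p = 8.0e-07) and 17 (median -0.189, adjusted p = 2.2e-06). Neither call held (adjusted p = 0.333 for each with an estimated correlation). For days 11 and 15 the later sets came from OP50 day 17 against day 6. Age-lowered genes then had medians of 0.203 and 0.207 (adjusted p = 0.0503 and 0.0102 with an estimated correlation). Age-raised genes had medians of -0.0731 and -0.0304 (adjusted p = 0.0626 and 0.333 with an estimated correlation). Without the 4 libraries rich in sperm transcripts, an alternative chosen after seeing the data, age-lowered genes were called lower at days 6 (adjusted p = 0.0227) and 17 (0.00301), and the call of age-raised genes at day 15 was lost (median 0.0563, 0.969). At day 11 the median of age-raised genes was then -0.205 (0.0224) and that of age-lowered genes 0.0815 (1.8e-05). Across genes, which are not independent replicates, the 2 changes had a Pearson's r of 0.09 at day 6, -0.16 at day 11, -0.22 at day 15 and -0.03 at day 17, and a Spearman's rho of 0.04, -0.13, -0.25 and 0.00.

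**Figure D3:**
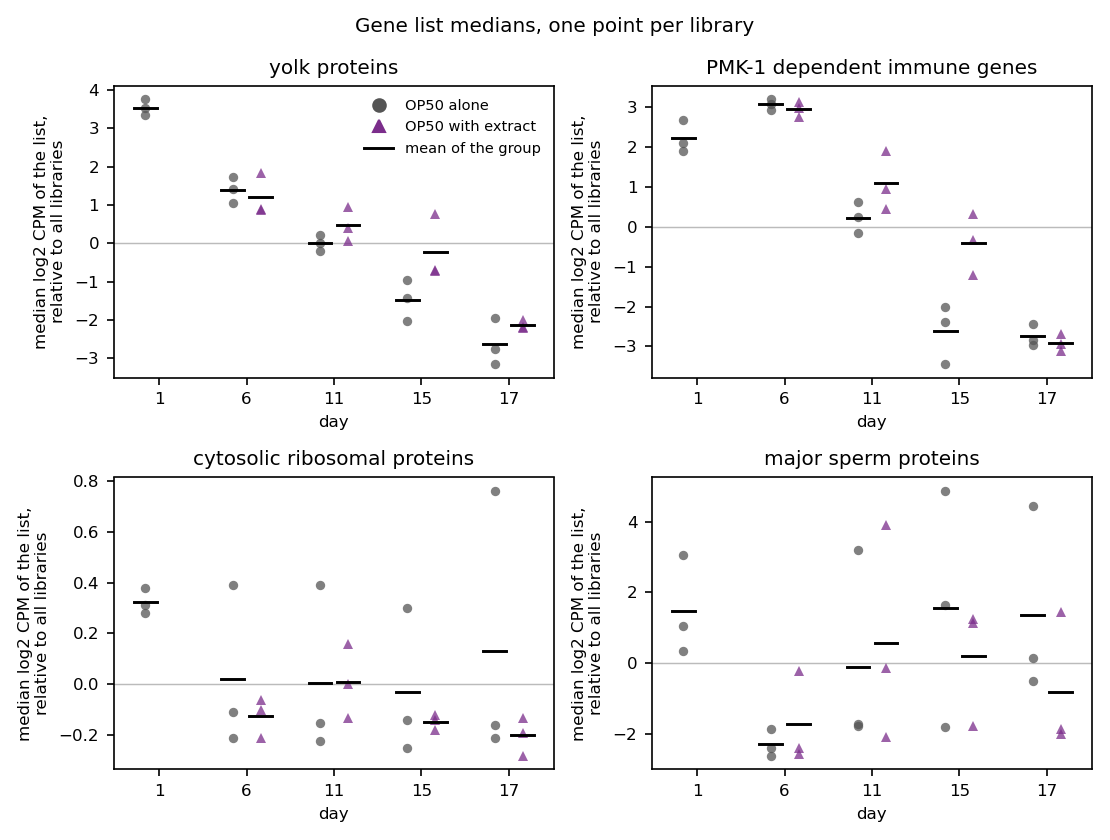
Median log2 CPM of 4 gene lists in each of the 27 libraries, relative to the mean of all libraries, by day, with colours for OP50 and BRE. At day 15 the PMK-1 list lies at -3.45, -2.01 and -2.40 in OP50 libraries and at 0.31, -1.21 and -0.34 in BRE libraries, while sperm protein medians reach 4.87 in 1 OP50 library of that day.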

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

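In this part, the tests of the day 15 lists without 1 library and of reads shared between neighbouring or overlapping genes were chosen after the results were seen. The matched random lists and the male and moulting markers were also aimed at patterns already seen in these data. The difference between the effect of BRE at day 17 and at day 6 was tested itself, and in 10 of 37 lists the 2 effects differed. These were yolk proteins (adjusted p = 0.0237, median difference 0.47), longevity and nutrient-sensing regulators (2.3e-04, 0.22), oxidative phosphorylation (0.0396, -0.10), ribosomal proteins (2.7e-09, -0.23), lysozymes (0.00709, -0.68), antimicrobial peptides (0.00406, -0.25), histones (5.2e-09, -0.31), FMRFamide-like neuropeptides (0.0371, -0.16), pharynx markers (0.0396, -0.34) and major sperm proteins (3.9e-15, lower at day 17). None was called with an estimated correlation, with adjusted p = 0.7 (lysozymes, sperm proteins and histones), 0.729 (longevity), 0.803 (pharynx), 0.879 (yolk and antimicrobial peptides), 0.924 (ribosomal proteins) and 0.987 (oxidative phosphorylation and FMRFamide-like neuropeptides) with an estimated correlation. Of the 10 calls 9 ended without at least 1 of the 12 libraries, and that of histones was kept, with medians of -0.585 without OP50 day 6 replicate 1 and -0.184 without OP50 day 6 replicate 3. Ribosomal proteins lost it only without OP50 day 17 replicate 1 (median 0.0708, adjusted p = 0.155), with medians of -0.469, -0.113, -0.382 and -0.404 without OP50 day 6 replicates 1 and 3 and OP50 day 17 replicates 2 and 3. The longevity list lost it only without OP50 day 17 replicate 1 (median 0.067, 0.186), with medians of 0.141, 0.425 and 0.127 without OP50 day 6 replicate 3, OP50 day 17 replicate 2 and BRE day 6 replicate 2. Sperm proteins lost it without BRE day 6 replicate 3 (0.0587), and antimicrobial peptides without OP50 day 17 replicate 2 (median -0.061, 0.198) or BRE day 17 replicate 1 (-0.164, 0.16). The median of antimicrobial peptides was -0.419 without OP50 day 17 replicate 1 and -0.383 without BRE day 17 replicate 3.

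The 5 other lists lost the call without several libraries. Yolk lost it without OP50 day 6 replicate 2 (median 0.258, adjusted p = 0.157), OP50 day 17 replicate 1 (0.183, 0.299) or 3 (0.411, 0.051), BRE day 6 replicate 2 (0.325, 0.167) or 3 (0.329, 0.121) or BRE day 17 replicate 3 (0.397, 0.0744), and its median was 0.801 without OP50 day 17 replicate 2. Lysozymes lost it without OP50 day 6 replicate 3 (median -0.319, 0.18), OP50 day 17 replicate 2 (-0.242, 0.123), BRE day 6 replicate 1 (-0.356, 0.336) or BRE day 17 replicate 1 (-0.44, 0.0844), with a median of -0.452 without BRE day 6 replicate 3. Oxidative phosphorylation lost it without OP50 day 6 replicate 2 (median -0.082, 0.137) or 3 (0.00454, 0.777), OP50 day 17 replicate 1 (0.0639, 0.255), BRE day 6 replicate 1 (-0.0751, 0.185) or 2 (-0.134, 0.0726) or BRE day 17 replicate 3 (-0.0363, 0.252). Its median was -0.278 without OP50 day 6 replicate 1, -0.166 and -0.249 without OP50 day 17 replicates 2 and 3, and -0.161 without BRE day 17 replicate 1. FMRFamide-like neuropeptides lost it without OP50 day 6 replicate 1 (median -0.114, 0.237) or 3 (0.0148, 0.947), OP50 day 17 replicate 3 (-0.146, 0.253), BRE day 6 replicate 2 (0.084, 0.677) or BRE day 17 replicate 1 (-0.0743, 0.232) or 3 (-0.126, 0.127), with medians of -0.481, -0.321 and -0.286 without OP50 day 6 replicate 2, BRE day 6 replicate 3 and BRE day 17 replicate 2. Pharynx markers lost it without OP50 day 6 replicate 1 (median -0.265, 0.11) or 3 (-0.158, 0.201), OP50 day 17 replicate 2 (-0.164, 0.171) or 3 (-0.0785, 0.319), BRE day 6 replicate 1 (-0.42, 0.0981) or 2 (-0.108, 0.566) or BRE day 17 replicate 1 (-0.31, 0.138) or 3 (-0.219, 0.198). Their median was -0.58 without OP50 day 6 replicate 2 and -0.517 without BRE day 6 replicate 3.

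The immune and yolk genes that fall with age were higher with BRE at day 15. For the PMK-1 list, 1 library as the source is argued against, since the median without BRE day 15 replicate 1 was 1.98 against 2.60. A share of 0.0008 of 10000 matched random lists had a median as high (their median 0.415, 95th percentile 1.02). Those lists were drawn gene by gene and do not allow for members that move together. The share therefore cannot decide on a general shift of age-lowered genes. For yolk genes the median fell from 1.23 to 0.381 without that library, and a share of 0.0826 of matched lists had a median as high (median 0.479, 95th percentile 1.49), so the yolk difference may rest on 1 library and on the general shift. A lag in the age of the BRE worms that followed the whole change from day 11 to day 17, on which the lists were matched, would move them alike. For the same reason the shares leave such a lag open for both lists. Its timing within those days was not tested, and the extract itself stays among the open explanations for both.

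Major sperm protein transcripts were high in 4 libraries after day 1, of both diets, OP50 day 11 replicate 1, OP50 day 15 replicate 3, OP50 day 17 replicate 1 and BRE day 11 replicate 1. Males among the worms could raise them. Over 24 libraries, deviations of list medians from their group mean were compared, which leaves out differences between days and diets. Those of 7 male neuron genes had a Spearman's rho of -0.01 with those of the sperm protein genes (permutation within groups, p = 0.96, r = -0.08). Larvae could as well, and the deviations of 10 moulting genes had a rho of -0.13 with those of the sperm protein genes (p = 0.627, r = -0.07). Both stay open, since the upper bound of r was 0.34 for each, and no explanation from the diets or days of the design was tested.

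The 9 genes called over days 6 to 17 were weighed against depth. For srlf-14, nlp-26 and idpp-1, reads shared with a paralog or with a gene on the opposite strand were weighed too. OP50 libraries of those days had 131.3 ± 17.2 and BRE libraries 138.2 ± 14.8 M counts (SD, n = 12 each), and with all of them thinned to 101.61 M 9 of 9 genes were still called, which argues against a difference in depth between the diets. Reads of srlf-12 counted for srlf-14 would give srlf-14 no larger a difference, but it was larger by 1.66 log2 units (SE 0.46); likewise nlp-26 exceeded the overlapping Y43F8C.3 by 1.74 (SE 0.19) and idpp-1 exceeded pat-12 by 4.02 (SE 0.43), which argues against reads of those genes. Of 100 splits within days, 1 (the real one) gave as many as 9 genes, and the highest other gave 2. The labels were shuffled in each day separately, which breaks up any series of libraries that runs through the days. These splits therefore cannot show how many genes a chance division of such series would give. An effect of the extract on these genes is a hypothesis found and tested on the same data, and a change confined to the stretch that nlp-26 or idpp-1 shares with the other gene was not tested. Reads of srlf-14 or srlf-13 counted for srlf-12, and reads of srh-112 counted for scl-25, were not tested either.

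For the other contrasts, splits of the same libraries were counted too. Single days have 10 splits, too few to tell, with the real one giving 3 genes at day 6 and the highest other 1, 2 and 0 at day 11, and 0 and 0 at days 15 and 17, where all 10 gave as many. At days 6 and 11, where numbers were taken to pair (less clearly at day 11), the 3 other splits that part every pair gave at most 0 genes. For OP50 at days 6, 11, 15 and 17 against day 1 the real split gave 6358, 6901, 9103 and 10399 and the highest other 282, 49, 92 and 1. For the difference between days and for day 17 minus day 6 all 100 splits gave as many as the real 0, and the highest other gave 1 and 11.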

How the results depend on the processing

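The alternatives without the libraries rich in sperm transcripts, and with an estimated correlation for the age-changed sets (from day 1 or from later days), were chosen after seeing the data. Of 2326 alternatives 14 turned the direction of a test, all of them for lists, whose medians changed sign in these and in 18 others where the test did not turn; those for named genes kept their direction in all (407 on the same side of the threshold and 74 weaker), and those for lists were the same in 1253 and weaker in 334. Gene counts with RLE size factors stayed within 1.5 times in every contrast. BRE at day 6 gave 5 genes with the replicate block within the day, 0 with only the libraries of the contrast and 13 with DESeq2. Day 11 gave 1 with only those libraries and 7 with DESeq2. Day 15 gave 14 with no filter, 8 with the replicate block over all libraries, 4 with the block within the day, 1 without the sperm-rich libraries and 59 with DESeq2. Day 17 gave 1 with either block and 3 with DESeq2. The averaged contrast gave 14 with no filter, 15 with the block within the day and 30 with DESeq2. DESeq2 gave 8 for the difference between days and 6 for day 17 minus day 6. A 2-fold threshold left 3659 genes at day 6 and 4425 at day 11 of OP50 against day 1. The cause was not tested for any of these, beyond fewer libraries or another threshold. Without each library in turn day 6 gave 0 to 3 genes, day 11 gave 1 to 2, day 15 gave 0 to 5, and the averaged contrast 6 to 11. In the averaged contrast Y38H6A.1 lost its call with the replicate block within the day or over all libraries, and ora-1, scl-25 and Y38H6A.1 lost theirs without the sperm-rich libraries. A left-out library leaves 2 in its group.

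Of 33 list calls at days 6 to 17, 2 were made with an estimated correlation, by construction stricter where members move together, and 1 with fry. The block within the day changed no other call at days 6 and 11 than those in the report. Elsewhere it added calls for 1 list at day 15, 3 at day 17, 2 in the averaged contrast (heat shock and chaperone genes lower, 0.00971 against 0.324, and neuron markers higher, 0.0292 against 0.104) and 3 for day 17 minus day 6. Adjusted p without each library in turn, where a direction turned, ran for ribosomal proteins from 2.6e-10 to 0.197 at day 6 (turned at 0.113 without OP50 day 6 replicate 1), from 9.5e-16 to 0.807 at day 15 (turned without OP50 day 15 replicate 1) and from 6.7e-21 to 0.155 for day 17 minus day 6 (turned without OP50 day 17 replicate 1). It ran for collagens from 2.6e-05 to 0.968 at day 6 (OP50 day 6 replicate 1) and 5.5e-10 to 0.643 averaged (BRE day 15 replicate 1). At day 11 it ran for glutathione S-transferases from 7.1e-05 to 0.93 and antimicrobial peptides from 1.8e-07 to 0.93 (both BRE day 11 replicate 3), and for muscle markers from 6.3e-07 to 0.283 (BRE day 11 replicate 2). For sperm proteins at day 15 it ran from 2.2e-14 to 0.704 (OP50 day 15 replicate 3). For day 17 minus day 6 it ran for oxidative phosphorylation from 2.8e-07 to 0.777 (turned at 0.255 without OP50 day 17 replicate 1) and FMRFamide-like neuropeptides from 1.4e-08 to 0.947 (turned at 0.677 without BRE day 6 replicate 2). Without the sperm-rich libraries sperm proteins at day 15 (0.748), and oxidative phosphorylation (0.188) and ribosomal proteins (0.0573) for day 17 minus day 6, turned. The cause was not tested. Age-lowered genes from later days were called lower with BRE at day 6 (8.0e-07) and day 17 (2.2e-06), and with an estimated correlation age-raised and age-lowered genes had adjusted p = 0.136 and 0.242 at day 11 and 0.242 and 0.0555 at day 15. With sets from later days and an estimated correlation they had 0.0626 and 0.0503 at day 11 and 0.333 and 0.0102 at day 15. Without the sperm-rich libraries age-lowered genes were called lower at day 6 (0.0227) and day 17 (0.00301), and age-raised genes were not called at day 15 (0.969). With all libraries thinned to 101.61 M counts 9 of 9 genes of the averaged contrast were still called; lower depths were not tested.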

Other observations

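Some of the genes higher with BRE lie near one another, and some of them, near or not, rise with age; these genes and values were chosen after the results were seen. srlf-12, srlf-14 and srlf-13 follow one another within 10891333 to 10896612 on the minus strand of chromosome IV. With BRE srlf-13 differed by 2.63 log2 units (SE 0.64, adjusted p = 0.467) by edgeR. ora-1 lies next to F57H12.6 (chromosome IV, 7975454 to 7976310), which differed by 1.39 (SE 0.29, adjusted p = 0.114), and the catechol-O-methyltransferase family gene comt-5, on chromosome V, by 1.14 (SE 0.23, adjusted p = 0.0757). In the reported fit edgeR called none of these 3, while DESeq2 called all 3. edgeR called F57H12.6 and comt-5 with no filter or with the replicate block over all libraries, srlf-13 and F57H12.6 with the block within the day, and comt-5 without each of 4 single libraries. In OP50 worms at day 17 against day 1 srlf-12 rose by 5.24, W03G1.5 by 3.33, srlf-3 by 3.23 and ora-1 by 3.08, while nlp-26 and idpp-1 fell (-1.62 and -3.61). srlf-14 (1.58, adjusted p = 0.141) and Y38H6A.1 (adjusted p = 0.15) did not pass with age, and scl-25, lower with BRE, rose by 2.24 with age (adjusted p = 0.0192).

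Across 19290 genes, which are not independent replicates, the BRE differences of 2 days had a Pearson's r between -0.24 (days 6 and 15) and 0.30 (days 15 and 17), and a Spearman's rho between -0.29 (days 11 and 17) and 0.26 (days 15 and 17).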
